A study of Mus musculus with 11 samples.

How the data were processed

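The samples are 11 arrays of splenic B cell RNA, in 4 groups set by strain (NOD or NR4) and culture (unstimulated or anti-IgM), with groups and replicate numbers taken from the sample titles. Each strain was represented by 3 lots of pooled spleens, and stimulated NOD cells were hybridized to 2 arrays, per the labels. Replicates within a group are thus separate pools of animals, but unstimulated and stimulated cultures of a strain come from the same lots. The labels do not say that a replicate number marks a lot, and the main model treats the arrays as independent. RNA was amplified in 1 cycle and labelled with biotin, per the labels.

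The deposited table holds values for 45101 probe sets, made with RMA per the submitters' processing notes and taken here as log2 values, a scale those notes do not state. RMA corrects background, normalizes by quantiles and summarises each probe set by median polish. The software and its version are not given in the sources used here. Every one of the 45101 probe sets has a median of exactly 0 over the 11 arrays, so the deposited values were also centred per probe set, a step the labels do not mention. The log base is not written in the file and was taken as 2, the scale on which RMA reports. Column medians lay between -0.0011 and 0.022. Centring leaves differences between arrays as they were but removes levels and detection calls, so a change in a gene near background cannot be told from one in an abundant gene. No pair of arrays held identical values (0 pairs). There is no count of reads on arrays, and the number of arrays limits the precision.

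Probe sets were named from the platform annotation, in which 34945 had 1 gene symbol, 932 had several and 9160 had none listed, and 64 were controls. Of the probe sets with 1 symbol, 99.4% were found by Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, and no symbol changed. That table was used only for names, chromosomes and gene order, because the files name no build. The design written before the data were examined took the probe set with the highest mean per gene and left out the dimmer genes as an alternative. Centred values have no means to rank, so the value of a gene is the median of its probe sets, which had been listed as the second choice, and the filter was not run. The planned windows of fixed length on chromosome 4 became 10 equal parts of the gene order for the same lack of a build. This gave 18193 genes, 49.5% of them with more than 1 probe set.

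One linear model with a mean for each of the 4 groups was fitted to all 11 arrays (7 residual degrees of freedom) with limma 3.58.1 in R 4.3.3, followed by empirical Bayes moderation and Benjamini-Hochberg adjustment within each of 7 comparisons, with a threshold of 0.05. All tests are two-sided, and a called gene is one past that threshold. The 7 comparisons are the strain difference in unstimulated cells, in stimulated cells and averaged over both, the response in NOD, in NR4 and averaged over both, and the interaction. Strain differences are NOD minus NR4 and responses are anti-IgM minus unstimulated. The 18 gene lists and 15 cell type marker lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 33 lists. Calls on chromosome 4 were set against other chromosomes with Fisher's exact test. Named genes follow a rule fixed at the same time. For the averaged comparisons these are up to 12 genes each way with the largest change among called genes whose arrays do not overlap, and up to 6 each way for the others. To these were added up to 4 called members of each list (or the 2 with the smallest p), called genes on chromosome 4, and Cd69, Egr1, Myc, Nr4a1 and Cd86. Names of predicted genes and clones could be passed over. The individual T and NK markers, and the interaction of Ccl3, were picked for the text among list members.

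Same-numbered arrays were checked for pairing before the calls of the fits were compared. For unstimulated NOD against NR4 the correlations of deviations were 0.59, 0.21 and 0.51. For unstimulated against stimulated NR4 they were 0.33, 0.22 and 0.47. All lay above the limit of 0.1 set for pairing by number. In NR4, however, unstimulated replicate 1 and stimulated replicate 2 also passed that limit, at 0.18. Stimulated NR4 replicate 2 correlated best with arrays numbered 1, so its pairing by number is uncertain. Comparisons with stimulated NOD have only 2 pairs, with values of 0.63 and 0.12 against unstimulated NOD and 0.37 and -0.12 against stimulated NR4, and pairing is not established for them. The 2 stimulated NOD arrays deviate as mirror images, so their correlations with any other array differ only in sign. The blocked fit adds the replicate number as a factor.

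The steps were tested on simulated data with the residual spread of the real genes and 200 changed genes per comparison over 18193 genes. Changes of 1 log2 unit were recovered in 91.7% for the strain difference averaged over both conditions, 92.5% for the averaged response, 61.4% for the response in NOD, 75.0% for that in NR4 and 32.8% for the interaction. False calls made up 2.52% to 7.69% of the calls over the 7 comparisons. The simulated noise was independent between arrays, without the deviations that same-numbered arrays share. These shares may therefore not hold for the real arrays or for comparisons with few changed genes. Alternatives changed the normalization, the probe set rule, the moderation, array weights, the threshold, the block, the arrays in the fit and each array in turn. Alternatives added after the data were examined are a block that places NOD anti-IgM replicate 2 with number 3, the lowest-numbered probe set of each gene, and the blocked fit without NR4 anti-IgM replicate 1.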

Results

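Gene expression was measured in splenic B cells of 2 mouse strains, NOD and NR4, with and without stimulation through the B cell receptor. NOD (NOD/ShiLtJ) mice develop autoimmune diabetes spontaneously. NR4 (NOD.NOR-Chr4/DvsJ) is a congenic strain in which part of chromosome 4 of NOD is replaced by the corresponding segment of the NOR strain. B cells of female mice aged 6 weeks were pooled from 7 to 8 spleens per lot and purified by magnetic depletion of other cells. They were cultured for 2 h in medium alone (unstimulated) or with 10 µg/ml of F(ab')2 fragments of goat antibody against mouse IgM, which cross-link the receptor. The 11 Affymetrix Mouse Genome 430 2.0 arrays comprise 3 of unstimulated NOD cells, 2 of stimulated NOD cells, 3 of unstimulated NR4 cells and 3 of stimulated NR4 cells. After probe sets were assigned to genes, 18193 genes were tested. Values are signals on a log scale, taken as log2 because the file does not state the base, and each probe set is centred on its median over the 11 arrays. Differences between groups are therefore reported and absolute levels are not, and the number of arrays limits the precision.

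The first comparison addressed which genes differ between NOD and NR4 B cells. Averaged over both conditions, 10 genes were higher and 12 lower in NOD (limma, Benjamini-Hochberg adjusted p below 0.05), and 13 of the 22 lie on chromosome 4. The largest difference was that of Zfp979, a zinc finger gene on chromosome 4, which was higher in NOD by 5.24 log2 units (SE 0.11, limma adjusted p = 2.5e-09). Dhrs3, which encodes a retinaldehyde reductase, was higher by 3.33 (SE 0.30, limma adjusted p = 0.00096). Cenps, a kinetochore and DNA repair gene, was higher by 2.04 (SE 0.11), and Padi2, a peptidylarginine deiminase, by 1.83 (SE 0.11). The other chromosome 4 genes higher in NOD were Zfp982 by 1.29, Angptl7 by 1.23 and Zfp691 by 0.80. Of the chromosome 4 genes lower in NOD, the pseudogene Gm13238 differed by -2.48 (SE 0.18), Cep85, a centrosomal protein gene, by -2.07 (SE 0.13), the pseudogene Znf41-ps by -1.52 and 9930104L06Rik by -1.40. The value of Cep85 averages 2 probe sets, and the second did not change the same way at an unadjusted p under 0.05 (limma). Lrp8, a lipoprotein receptor, differed by -0.74 and Sh3bgrl3 by -0.61.

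A further 9 genes on other chromosomes differed. Icam2, an adhesion molecule gene on chromosome 11, was higher in NOD by 3.83 log2 units (SE 0.06, limma adjusted p = 3.9e-10), the smallest adjusted p of the comparison. Stat4, a transcription factor of cytokine signalling on chromosome 1, was higher by 0.68 (SE 0.09), and the ubiquitin ligase Rnf125 on chromosome 18 by 0.67 (SE 0.10). Lower in NOD were Srgap3 on chromosome 6, which differed by -2.15 (SE 0.12), and Hsd11b1, the enzyme that regenerates active glucocorticoid, by -1.26 (SE 0.14). Zgrf1 on chromosome 3 differed by -1.13, Akr1e1 on chromosome 13 by -1.08, the signalling regulator Ubash3b on chromosome 9 by -0.66 and the immunoglobulin segment Igkv4-72 on chromosome 6 by -0.62. Akr1e1, like Cep85, averages 2 probe sets of which the second did not change the same way at an unadjusted p under 0.05. Icam2, Stat4, Rnf125, Hsd11b1, Zgrf1 and Igkv4-72 rest on 1 probe set each. For them a change in expression cannot be told from a sequence difference under the probes. In each of the 22 genes, the arrays of the strains did not overlap within either condition. Within unstimulated cells alone, with 3 arrays against 3, chance gives such a separation for 10% of genes. Arrays with the same replicate number deviated together. At an unadjusted p under 0.05 (limma) there were 799 genes, where 910 are expected by chance, and 1559 with that number as a block. In unstimulated cells alone there were 281, and 648 with the block. Averaged over both conditions, 37 genes passed adjustment with the block, 18 higher and 19 lower, among them all 22. Without NOD anti-IgM replicate 2 the count was 12.

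**Figure D1:**
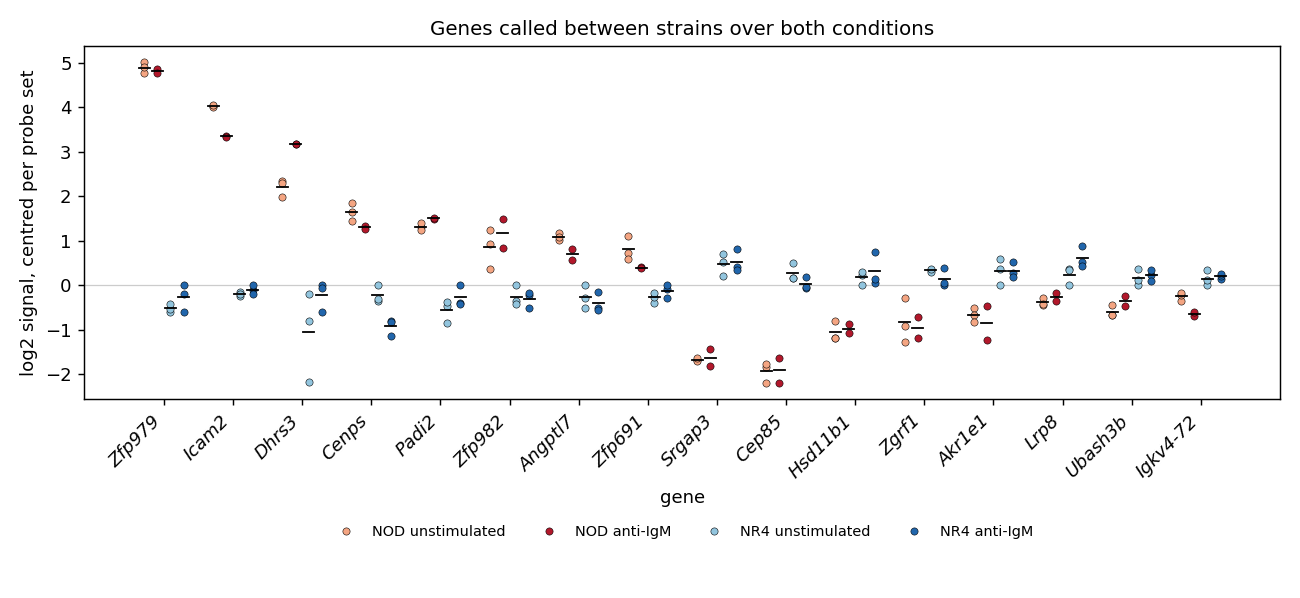
Centred log2 signal (vertical axis) of 16 genes called between the strains (horizontal axis), 8 higher and 8 lower in NOD, with a point per array, coloured by group, and a bar at each group mean. Zfp979 and Icam2 stand farthest apart, by 5.24 and 3.83 log2 units over both conditions.

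Called genes were concentrated on chromosome 4. There, 13 of 1087 tested genes passed (1.20%), against 9 of 16943 on the other chromosomes (0.053%), an odds ratio of 22.8 (95% interval 8.98 to 60.5, two-sided Fisher's exact test p = 3.9e-11). With each array left out in turn it was 24.7 to 78.6, the highest without NOD anti-IgM replicate 2. Of the 13 genes, 8 fell in the ninth of 10 equal parts of the chromosome's gene order, the part that runs from Pla2g2a to Cenps. They are Padi2, Dhrs3, Znf41-ps, Gm13238, Zfp982, Zfp979, Angptl7 and Cenps. None of the 109 genes of the last part passed by limma, and none there reached an unadjusted p under 0.01. Over the whole chromosome 4.88% of genes had an unadjusted p under 0.01, where chance gives 1%. Response genes showed no such concentration, with 14 of 1087 on chromosome 4 and an odds ratio of 0.81 (95% interval 0.44 to 1.39). Coordinates are not given because the files name no genome build.

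**Figure D2:**
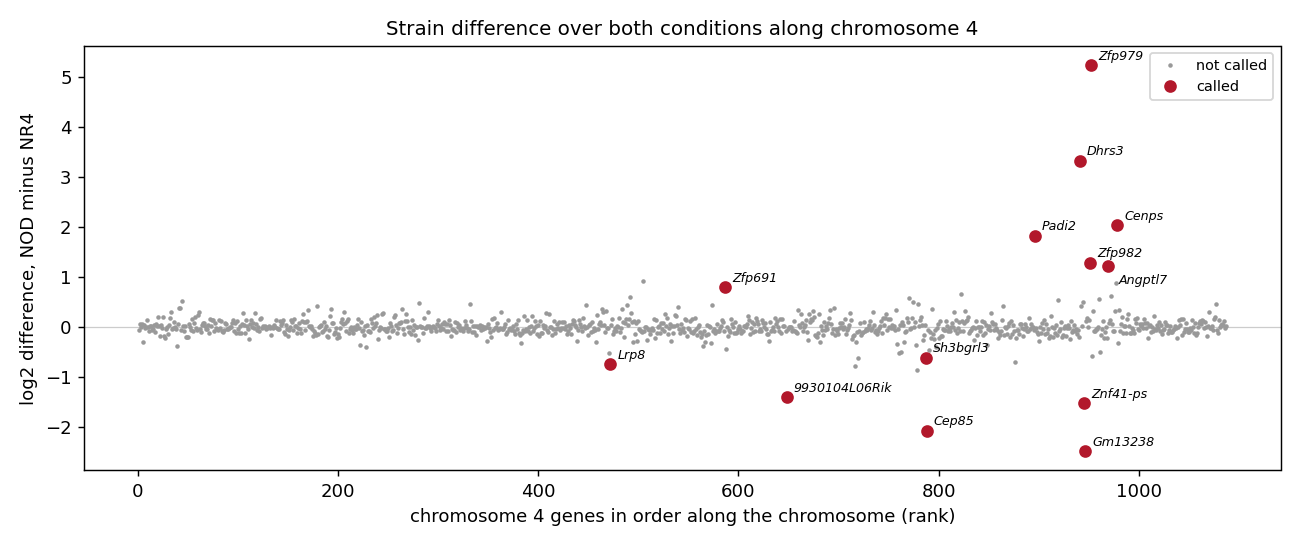
Log2 difference between NOD and NR4 over both conditions (vertical axis) of the 1087 genes of chromosome 4, in their order along the chromosome (horizontal axis, rank). The 13 called genes are red and named, and 8 of them lie in the ninth of 10 equal parts of the gene order.

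Within single conditions the same kinds of difference were found. In unstimulated cells 7 genes were higher and 4 lower in NOD, and 9 of these 11 lie on chromosome 4. After quantile normalization of the deposited values 8 were higher and 7 lower. Zfp979 differed by 5.40 (SE 0.15), Icam2 by 4.22 (SE 0.08), Padi2 by 1.88 (SE 0.15), Cep85 by -2.21 (SE 0.17) and Srgap3 by -2.15 (SE 0.16). In stimulated cells 5 genes were higher and 4 lower, and 7 of the 9 lie on chromosome 4. Zfp979 differed there by 5.08 (SE 0.16), Icam2 by 3.45 (SE 0.09) and Cenps by 2.22 (SE 0.16). All 9 genes called in stimulated cells were also called, in the same direction, in unstimulated cells. These are separate arrays but come from the same lots of spleens per strain, so the agreement is not an independent replication. The other 2 of the 11, Angptl7 and Zfp691, had the same direction and an unadjusted p under 0.05 in stimulated cells. Without NOD anti-IgM replicate 1 the count in stimulated cells was 4.

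Among the gene lists fixed beforehand, single members rarely differed between strains. Of the 26 measured immune genes from the Idd9/Idd11 part of chromosome 4, the region linked to diabetes resistance, Padi2 alone passed over all genes tested, while 5 were higher and 1 lower when adjusted over the list alone. With camera's preset correlation, 15 of 33 lists shifted, and none did with an estimated correlation. The 34 interferon-stimulated genes had a median of -0.20 log2 in NOD (camera adjusted p = 4.6e-09, adjusted p = 0.37 with an estimated correlation). None passed over all genes tested and 1 was lower adjusted over the list alone. Oasl2, an antiviral gene, was at -1.28 (SE 0.28, limma adjusted p = 0.27) and Mx1 at -0.99 (SE 0.26, limma adjusted p = 0.54). The 22 immediate-early transcription factors had a median of 0.21 (camera adjusted p = 1.6e-06, adjusted p = 0.16 with an estimated correlation), with 0 members called and 3 higher adjusted over the list alone. Plasma cell markers had a median of -0.14 (camera adjusted p = 0.00081, adjusted p = 0.16 with an estimated correlation) and no member passed, with Xbp1 at -0.23. Markers of NK and cytotoxic cells, which the depletion should remove, had a median of 0.32 (camera adjusted p = 0.0098, adjusted p = 0.44 with an estimated correlation), and 0 of 11 passed. The list passed in unstimulated cells (camera adjusted p = 0.0041), though not with an estimated correlation, and did not pass in stimulated cells (camera adjusted p = 0.19). No list passed the interaction with all arrays, so the shift is not shown to differ between the conditions. The markers of this list also differed by replicate number, as given below. With that number as a block the averaged shift had an adjusted p = 0.0074. The T cell list had a median of 0.07 and did not shift, with Cd4 at -0.72 (SE 0.12, limma adjusted p = 0.072).

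The second comparison addressed the response to anti-IgM. Averaged over both strains, 130 genes rose and 153 fell (limma, adjusted p below 0.05), 29 and 15 of them by at least 2-fold. The largest rise was that of Bex1, by 2.28 log2 units (SE 0.41, limma adjusted p = 0.023), followed by Gpr176, an orphan receptor, by 2.14 (SE 0.24) and the small Maf protein Maff by 1.90 (SE 0.21). Chemokine genes Ccl4 and Ccl3 rose by 1.73 (SE 0.13) and 1.73 (SE 0.24), and Il10, an anti-inflammatory cytokine, by 1.57 (SE 0.13). Among the largest falls were those of Cpm, a carboxypeptidase, by -2.20 (SE 0.31), Klhl14 by -1.84 (SE 0.22), the kinase Lrrk2 by -1.71 (SE 0.14) and the urea transporter Slc14a1 by -1.55 (SE 0.17). Sertad4 changed by -1.44, Edaradd by -1.43, Wfdc21 by -1.36, Vpreb3 by -1.28 and Tmem26 by -1.25. Nxpe2 changed by -1.20 with the smallest adjusted p (SE 0.07, limma adjusted p = 7.1e-05). Its lowest-numbered probe set alone changed by -0.047 and that of Edaradd by -0.63, and neither passed. In 275 of the 283 genes the arrays of the conditions did not overlap within either strain. With the replicate number as a block 558 genes passed, 228 higher and 330 lower, including all 283. Without NOD anti-IgM replicate 2 the count was 76.

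**Figure D3:**
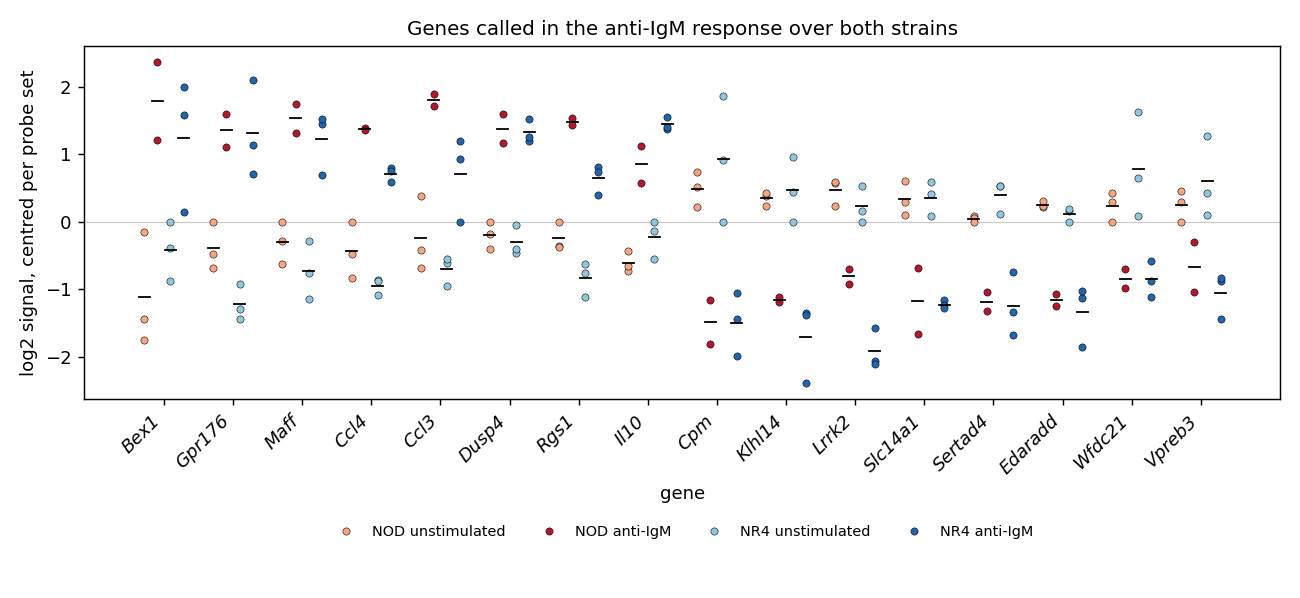
Centred log2 signal (vertical axis) of 16 genes called in the anti-IgM response (horizontal axis), 8 rising and 8 falling, with a point per array, coloured by group, and a bar at each group mean. Bex1 rose by 2.28 and Cpm changed by -2.20 log2 units on average over both strains.

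Of 22 measured immediate-early transcription factors, 13 rose, 0 fell and 9 did not pass, and 15 rose when adjusted over the list alone. Besides Maff these included Myc, the growth regulator, by 1.46 (SE 0.18), Nr4a1, a nuclear receptor induced by antigen receptor signalling, by 1.43 (SE 0.20), Fosb by 1.23, Egr2 by 1.21 (limma adjusted p = 7.1e-05) and Atf3 by 1.12. Egr1 rose by 0.32 (SE 0.06, limma adjusted p = 0.032). The list shifted upward with the preset correlation (camera adjusted p = 2.3e-20) and not with an estimated one (adjusted p = 0.059). In the NF-kB list 4 of 18 genes rose and 0 fell, namely the subunit gene Rel by 1.09, Nfkbid by 0.84, Nfkbiz by 0.42 and Nfkbie by 0.41 (adjusted over the list alone, 7 rose and 2 fell). Its shift had a camera adjusted p = 0.00036 and an adjusted p = 0.23 with an estimated correlation. Of 24 cytokine and chemokine genes, 3 rose and 1, Il12a, changed by -1.21 (SE 0.17), with 7 rising and 1 falling adjusted over the list alone (adjusted p = 0.26 with an estimated correlation). In the list of negative feedback genes, Dusp4, a MAP kinase phosphatase, rose by 1.60 (SE 0.12), Rgs1 by 1.60 (SE 0.12) and Spry1 by 1.23. Dusp6 changed by -0.63 and the inhibitory receptor gene Cd22 by -0.99, with 21 of 26 not passing and an adjusted p = 0.32 with an estimated correlation.

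Of 13 pan B cell markers, 5 fell and 0 rose, and 6 fell adjusted over the list alone. These were Cd22, the receptor subunit Cd79b by -0.62 (SE 0.10), Cd37 by -0.54, Ms4a1, which encodes CD20, by -0.51 and Fcrla by -0.47 (camera adjusted p = 6.2e-06, adjusted p = 0.23 with an estimated correlation). Of 32 B cell receptor signalling genes, Nfatc1 rose by 0.79, while Rasgrp3 changed by -0.93 and Cd79b by -0.62, and the list had an adjusted p = 0.38 with an estimated correlation. In the list of quiescence and migration genes, Btg2 (-0.65), Sesn1 (-0.59) and Ccng2 (-0.51) fell and Gpr183, a migration receptor, rose by 0.76, with 23 of 27 not passing (adjusted p = 0.35 with an estimated correlation). Irf4, needed for plasma cell differentiation, rose by 0.79, and Rgs13 of the germinal centre list by 1.20. With the lowest-numbered probe set Cd37 was at -0.27, Ccng2 at -0.23 and Irf4 at 0.30, none of them called.

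Of the other lists, the 41 ribosome biogenesis genes had a median of 0.14 and 33 positive members. None passed over all genes tested and 2 rose adjusted over the list alone (camera adjusted p = 2.0e-05, adjusted p = 0.32 with an estimated correlation). Glucose uptake and glycolysis genes Hk2 and Slc2a1 rose by 0.39 and 0.38, with 15 of 17 not passing. Among 24 genes of protein and amino acid stress, Ppp1r15a rose by 0.77, Atf4 by 0.32 and Dnajb9 by 0.32 (camera adjusted p = 0.00036, adjusted p = 0.080 with an estimated correlation). No member of the interferon, mitosis, antigen presentation, oxidative phosphorylation or B cell activation surface protein lists passed. Cd69 and Cd86, early surface markers of activation, were at 0.17 (SE 0.07, limma adjusted p = 0.35) and 0.26 (SE 0.12, limma adjusted p = 0.50). Among markers of other cells, Cd5, shared by the T cell and B-1 cell lists, rose by 0.95, Ms4a6c of the monocyte list by 0.55 and Itgax of the dendritic cell list by 0.50, while Pecam1 of the endothelial list changed by -0.97.

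In NR4 cells alone, 30 genes rose and 45 fell (limma, adjusted p below 0.05). Gpr176 rose by 2.54 (SE 0.32), Maff by 1.95, Il10 by 1.67 (SE 0.17), Ccl4 by 1.65, Dusp4 by 1.63 and Rgs1 by 1.48. Cpm changed by -2.42, Klhl14 by -2.18, Lrrk2 by -2.15 (SE 0.18, limma adjusted p = 0.0020), Sertad4 by -1.64 and Slc14a1 by -1.59. With the replicate number as a block 229 genes passed, 82 higher and 147 lower, and without NR4 unstimulated replicate 1 the count was 21. After quantile normalization of the deposited values, which forces the same spread of centred values on every array, 9 rose and 6 fell. In NR4 anti-IgM replicate 1 the control transcripts had a mean difference between 3' and 5' probe sets of 0.96 log2 units. It was -0.08 to 0.29 in the unstimulated arrays and 0.04 to 0.23 in the other stimulated arrays. Without NR4 anti-IgM replicate 1, 18 genes rose and 25 fell. In NOD cells alone, 18 genes rose and 3 fell, and 6 rose and 1 fell after quantile normalization. Ccl4 rose by 1.81 (SE 0.20), Rgs1 by 1.73 (SE 0.18), Dusp4 by 1.58, Il10 by 1.46, Gdap10 by 1.45 and Atf3 by 1.32, while Edaradd changed by -1.41, Nxpe2 by -1.10 and Icam2 by -0.68 (SE 0.09). In NR4 the centred mean of Icam2 was -0.19 unstimulated and -0.10 stimulated, so no fall was seen there, though the gene did not pass the interaction test. Whether its signal in NR4 lies near background is not known. With the lowest-numbered probe set Nxpe2 was at 0.029 and Edaradd at -0.28 in NOD, neither called. No stimulated NOD array is numbered 3. Without a block, comparisons that use stimulated NOD cells, including the averages and the interaction, can therefore take in part of the difference by replicate number. With the number as a block 36 genes rose and 16 fell in NOD. A fixed block of lot within strain left 2 rising and 0 falling, and pairing is not established for NOD. Only 2 arrays represent stimulated NOD cells, and leaving out any 1 of the 5 NOD arrays left 0 to 4 called genes, with 0 in the absence of NOD anti-IgM replicate 2.

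The third comparison addressed whether the response differs between the strains. No gene passed the interaction test (limma, 0 genes with and without the replicate block). At an unadjusted p under 0.05 there were 255 genes, where 910 are expected by chance. With the block there were 977. None of the 33 lists shifted by camera with all arrays, and 7 did without NR4 unstimulated replicate 2. On simulated data with noise independent between arrays, the same test recovered 32.8% of genes whose responses differed by 1 log2 unit and 85.9% of those differing by 2. Smaller differences would thus mostly have been missed. Of the 75 genes called in NR4, 73 changed in the same direction in NOD and 70 of these had an unadjusted p under 0.05 there. Over all 18193 genes the responses correlated with r = 0.53 (Spearman's rho 0.35) and had the same sign in 60.0%, a correlation across genes, which are not independent replicates. The responses share no arrays. Ccl3, for example, rose by 2.04 in NOD and by 1.41 in NR4, a difference of 0.63 (SE 0.49).

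**Figure D4:**
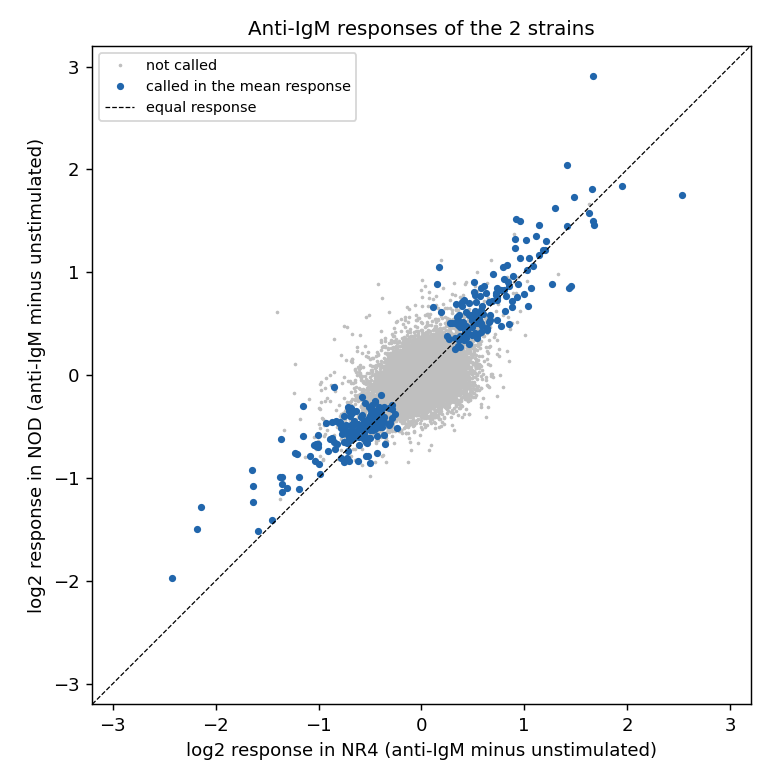
Log2 response to anti-IgM in NOD (vertical axis) against that in NR4 (horizontal axis), with a point per gene and a dashed line of equal response. The 283 genes called in the mean response are blue, and over all 18193 genes r is 0.53.

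The arrays also differed by replicate number. The first component of the deviations from the group means held 46.0% of their variance and set the arrays numbered 1 apart from those numbered 3. Between arrays of different groups, deviations correlated at a mean of 0.33 over 15 pairs with the same number and -0.17 over 30 pairs with different numbers. The 2 stimulated NOD arrays deviate from their mean as mirror images, as any 2 arrays of a group of 2 must, so replicate 2 is not placed independently of replicate 1. With groups in the model, 969 genes were higher and 1537 lower in the arrays numbered 3 than in those numbered 1 (limma, adjusted p below 0.05). Among them were lower values of NK and T cell markers, including Gzma by -1.05, Ccl5 by -0.99, Nkg7 by -0.88 and Cd3e by -0.48.

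**Figure D5:**
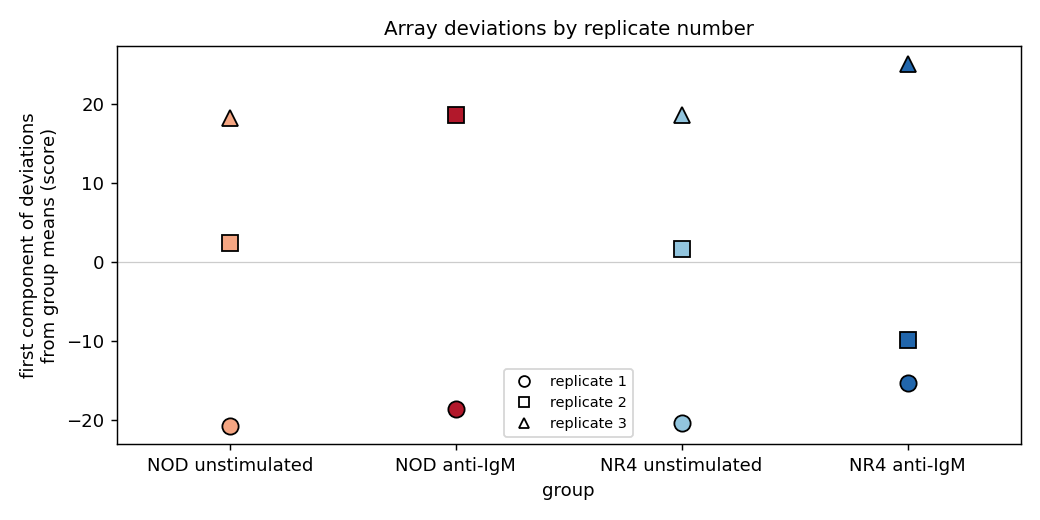
Score of each array on the first component of the deviations from group means (vertical axis), by group (horizontal axis), with the replicate number as the symbol. Arrays numbered 1 lie below 0 in every group and those numbered 3 above 0, and the 2 arrays of stimulated NOD cells are mirror images by construction.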

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

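The odds ratio on chromosome 4 was planned before the data were examined, as a check of the labels. Its use to weigh a cause was chosen only after the pattern was seen. The tests of RNA integrity and of the lot of NOD anti-IgM replicate 2 were also chosen after the patterns were seen, and the others before. Groups of 2 or 3 arrays are too small for a test of single outlying arrays.

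Signals outside the comparisons were seen in control and unnamed probe sets. In NR4 anti-IgM replicate 1, the beta-actin and Gapdh control transcripts had a mean 3' minus 5' difference of 0.96 log2 units, above the -0.08 to 0.29 of the 6 unstimulated arrays. The other stimulated arrays lay at 0.21 and 0.13 in NOD and 0.04 and 0.23 in NR4. Of the unstimulated arrays only NR4 replicate 3, at 0.29, lay above 0. The 5' beta-actin signal was lower in every stimulated array (-1.30 to -0.14) than in every unstimulated one (0 to 0.08). This measure thus ran with stimulation, and whether it contributes to the response calls was not tested. Of 10092 probe sets with no gene name or several, 15 differed between strains over both conditions, 6 higher and 9 lower in NOD, and were not part of the comparisons of genes. The largest difference among them was -4.94 log2 units in NOD (SE 0.12, limma adjusted p = 3.5e-08), in a probe set without a gene name, followed by another at -4.33 (SE 0.22). No interaction of strain and stimulation passed for any gene or, with all arrays, for any list.

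The first pattern is that of strain calls on chromosome 4. The design names a biological candidate, the chromosome 4 segment carried by NR4. The odds ratio of 22.8 (95% interval 8.98 to 60.5) was planned as a check of the labels and meets that check. It cannot show that the segment changed expression. A sequence difference under the probes within the segment could give the same concentration without a change in expression. Among 15 genes on the chromosome with a strain-called probe set and a further one, the further one moved the same way in 40% (95% interval 16.3% to 67.7%), against 68.0% (62.4% to 73.1%) of 309 genes called in the response. The intervals overlap, so by the bound set beforehand this leaves open how many of the differences reflect the probes and how many expression. Overlap of intervals is not itself a test of the difference. The 15 genes were called in a fit of single probe sets. Of the 13 called genes on the chromosome only Cep85, Zfp982 and Lrp8 are among them. A further probe set moved the same way for Zfp982 and Lrp8 and not for Cep85. Several of the largest differences, those of Zfp979, Dhrs3, Cenps and Padi2, rest on 1 probe set each.

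The second pattern is that arrays deviate together by replicate number, and other cell types carried along in some lots may account for part of it, since the largest of 8 marker lists' median differences between numbers 3 and 1 was 0.59 log2 units in size, that of NK and cytotoxic cells, which were lower in number 3 with 5 of 11 markers called (camera adjusted p = 0.036, adjusted p = 0.79 with an estimated correlation). T cell markers had a median of -0.34 with 6 of 17 called lower, among them Cd3e at -0.48 and Thy1 at -0.53, but the list did not pass (camera adjusted p = 0.098, adjusted p = 0.77 with an estimated correlation), and magnetic depletion should remove both cell types. Shifts like that of the T cell list were not particular to markers of other cells. B-1 cell markers had a median of -0.32 (camera adjusted p = 0.098) and mitosis genes 0.29 (camera adjusted p = 0.093). Of the 101 markers in the 8 lists, 14 were called lower and 3 higher, against 1537 and 969 of all 18193 genes. How much of the pattern comes from other cell types stays open. RNA integrity stays open, since over the 11 arrays the 3' minus 5' difference correlated with the first component at r = -0.11 (permutation p = 0.82, 95% interval -0.67 to 0.52) and rho = 0.21 (permutation p = 0.54), and at r = 0.20 without the 2 farthest arrays. That NOD anti-IgM replicate 2 comes from the lot of number 3 cannot be told either, because its coefficient of 0.69 on the number 3 profile against 0.13 on that of number 2 comes from a regression that placed only 3 of 6 other arrays at their own number.

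The third pattern is the larger number of calls in NR4 (75) than in NOD (21). One array fewer in the stimulated NOD group was tested by leaving out each stimulated NR4 array, and the lowest count, 43, stayed above the limit of 31.5, which is 1.5 times that of NOD. That test left out the unstimulated arrays. Without NR4 unstimulated replicate 2 or 3 the counts were 49 and 34, also above the limit. Without NR4 unstimulated replicate 1, with as many arrays as NOD, the count was 21, as in NOD, so the number of arrays stays open. A larger response in NR4 was tested by the major axis slope of the NOD on the NR4 response over the 283 genes called on average, which was 0.94, with 0.90 to 0.97 when each array was left out, and its distance of 0.060 from 1 is smaller than that range of 0.074. These genes were selected for a change averaged over the strains, which can draw the slope toward 1, and the range is not a standard error. Over all 18193 genes, most of them not called, the slope was 0.74, and no range was computed for it. A larger response in NR4 therefore stays open too.

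Other splits of the same arrays were counted for 4 comparisons. For the averaged response, 1 of 100 splits within strains, the real one, reached its 283 genes, a share under 0.05, and the highest other gave 0. Of these splits 18, the real one included, part as many same-numbered pairs, too few for a share under 0.05, and the highest other among them gave 0. For the averaged strain difference, 3 of 100 splits within conditions reached 22 genes, a share under 0.05, but the highest other gave 1963. In 4 of the drawn splits the smaller group held both arrays of number 3 of unstimulated cells with NR4 anti-IgM replicate 3 and NOD anti-IgM replicate 2. The 2 with an array of number 2 as the other member gave 1963 and 1484 genes and the 2 with an array of number 1 gave 0. Other drawn splits held the same arrays together within the larger group, and these gave 0 genes. The high counts arose where numbers 1 and 3 were fully apart. A further split with them fully apart gave 0, however, so that separation alone does not account for the high counts. Of the drawn splits 15, the real one included, part as many same-numbered pairs, again too few for a share under 0.05, and the highest other among them gave 0 genes, and with the number as a block 37 genes passed. For unstimulated strains (11 genes) and the NR4 response (75 genes) there are only 10 splits, too few for a share under 0.05, and in both 1 split, the real one, reached the count while the highest other gave 0.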

How the results depend on the processing

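The alternatives with NOD anti-IgM replicate 2 placed with number 3, with the lowest-numbered probe set and with a block but without NR4 anti-IgM replicate 1 were chosen after seeing the data. The filter on dim genes was not run, since centred values have no levels, and signal over background is not known for the same reason. Counts are given for the strain difference (unstimulated 11, anti-IgM 9, both 22 genes), the response (NOD 21, NR4 75, both 283 genes) and the odds ratio of chromosome 4 (22.8). Where no cause is named, the cause was not tested. The interaction called 0 genes under every alternative run. Shifting each array to the same median moved no count by over 1.5 times.

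Quantile normalization gave 7 genes for NOD and 15 for NR4. Applied to centred values, it forces the same spread of deviations on every array, whether or not the spread differs for real reasons. Testing all probe sets gave 26, 17 and 53 for the strain differences and 456 for the averaged response, counted in probe sets. A trended and robust prior, whose trend has no signal level to follow in centred values, gave 2, 2 and 9 for the strain differences and 0, 0 and 135 for the responses. Array weights gave 127 for unstimulated strains, 35 for both conditions, 94 for NOD and 506 for both strains, with the number 2 arrays of unstimulated NOD and NR4 weighted by 7.28 and 5.15. Requiring a log2 change of at least 1 left 36 for NR4 and 44 for both strains. The threshold of 0.01 left 13 for the averaged strain difference and 2, 14 and 72 for the responses, with an odds ratio of 52.4 for chromosome 4. Fitting only the groups compared, with fewer arrays, left 4 for stimulated strains, 0 for NOD and 9 for NR4.

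The replicate block by number gave 37 for the averaged strain difference, 52 for NOD, 229 for NR4 and 558 for both strains, and changed no other count of calls by over 1.5 times. Pairing is not established for NOD. Of the 11 arrays, 2 did not correlate best with their own number, 1 of them NOD anti-IgM replicate 2, which mirrors replicate 1. The other, NR4 anti-IgM replicate 2, correlated best with number 1, so its place in the block is uncertain. A fixed block of lot within strain gave 2, 96 and 290 for the responses, and a random one 91, 353 and 756. With NOD anti-IgM replicate 2 placed with number 3, the block gave 60, 253 and 620. Without NR4 anti-IgM replicate 1 and with the block, the responses counted 52, 115 and 617.

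With an estimated correlation, 0 lists shifted for each of the strain differences (9, 10 and 15 with the preset one), 1 for NOD (of 9), 0 for NR4 (of 8) and 0 for both strains (of 13). The lowest-numbered probe set gave 6 lists for stimulated strains. Over genes called in the averaged response, the correlation of the strains' responses was 0.96, where 0.53 holds over all genes, and these genes were selected for a change averaged over the strains. Of single genes, 2 turned with the lowest-numbered probe set. Nxpe2 in NOD went to 0.029 and Bcl2l11 between strains to -0.058, neither called. Over all alternatives and left-out arrays, 799 values of named genes lost their call, 31 gained one and 3648 kept their side and direction.

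Leaving out each array in turn gave these ranges. A group left with 1 array is assumed to vary like the others. Counts were 8 to 11 for unstimulated strains, 4 to 9 for stimulated strains (4 without NOD anti-IgM replicate 1), 12 to 21 for both (12 without NOD anti-IgM replicate 2), 0 to 4 for NOD, 21 to 50 for NR4 and 76 to 273 for both strains. The odds ratio of chromosome 4 was 24.7 to 78.6 (78.6 without NOD anti-IgM replicate 2), and the correlation of responses 0.40 to 0.55. Lists called were 6 to 11, 3 to 11 and 7 to 17 for the strain differences, 8 to 10, 4 to 12 and 11 to 14 for the responses, and 0 to 7 for the interaction (7 without NR4 unstimulated replicate 2).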

Other observations

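Other lists fixed beforehand held single genes that changed in the averaged response (limma, adjusted p below 0.05). S1pr3, a sphingosine phosphate receptor of marginal zone B cells, rose by 0.89 (SE 0.09), while Cd1d1 of the same list changed by -0.39 (SE 0.08), and 12 of 14 members did not pass. Of the B-1 cell list, Cd5, a negative regulator of antigen receptor signalling, rose by 0.95 and Plscr1 by 0.74. Of the transitional list, Myb rose by 0.42. Cd55 of the follicular list changed by -0.58, E2f2 of the cell cycle list by -0.79, and Id3, an inhibitor of E proteins that lies in the Idd9/Idd11 list, by -0.77. The apoptosis regulator Bcl2l11, which encodes BIM, rose by 0.31 and Idi1 of cholesterol synthesis by 0.43. With the lowest-numbered probe set Cd1d1, Myb, E2f2, Bcl2l11 and Idi1 kept their direction but were not called. None of these lists shifted as a whole (camera adjusted p 0.22 or more).

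Between the strains, lists that shifted with the preset correlation and not with an estimated one also include those of negative feedback genes (median 0.13) and of quiescence and migration genes (median 0.10), both with 0 members called. Rgs1 was at 0.71 in NOD (SE 0.12, limma adjusted p = 0.085), and Gpr183 at 0.22. Markers of germinal centre B cells had a median of 0.12, those of follicular B cells 0.18 and those of stromal and endothelial cells -0.08, the last with Kdr at -0.75 (SE 0.14, limma adjusted p = 0.12). Markers of monocytes, neutrophils, dendritic cells, erythroid cells and megakaryocytes did not shift between strains, with medians from -0.06 to 0.00, and none of their members passed.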
